A study of Mus musculus with 11 samples.

How the data were processed

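Macrophages were grown from bone marrow of wild-type C57Bl/6 mice for 1 week in medium with 5 ng/ml macrophage colony-stimulating factor and used 24 hours after replating. They were left untreated or treated for 1 hour with 100 ng/ml LPS, alone or together with 10 µM prostaglandin E (PGE), and 250 ng of total RNA per sample was measured on Affymetrix mouse whole-transcript gene arrays. Of 12 arrays made, the authors left out 1 of the LPS group for quality, so 4 untreated, 3 LPS and 4 LPS plus PGE arrays were used. The labels do not say whether replicates were separate mice or separate cultures. The p-values therefore measure only the spread between these samples, and the number of arrays limits the precision.

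The values are those the authors deposited, on a log2 scale. That scale was inferred from RMA, a background correction, normalization and summary method named in the submitters' processing notes, and from the range of the values (1.20 to 13.81). The submitters' processing notes also name Affymetrix Power Tools, R 2.13.1 and Partek, without giving their roles. The genome build is not given in the sources used here, and no coordinates are reported. Raw array files were not used here.

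The deposited table has 35309 probe sets. Of these, 21143 carried 1 gene symbol, 1870 several and 12296 none. Where a gene had several probe sets (1379 genes), the one with the highest mean over all arrays was taken, which gave 18755 genes. Current gene names were looked up for 21110 probe sets by their gene identifier, and 0 symbols changed. Probe sets without a symbol were left out of the comparisons and are described in the closing section.

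A group-means model was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3 (8 residual degrees of freedom, 3.77 prior degrees of freedom), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The 3 comparisons were LPS against untreated, LPS plus PGE against untreated, and LPS plus PGE against LPS, each two-sided. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and a 2-fold change is an absolute log2 fold change of at least 1. Treatment-responsive genes were chosen on the mean of the 7 treated arrays minus untreated, because the error of that difference is uncorrelated with that of LPS plus PGE minus LPS. An effect of PGE itself enters that mean, so the choice on LPS against untreated is given beside it.

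Of 24 gene lists, 16 covered pathways: NF-kB feedback, inflammatory cytokines, chemokines, immediate-early transcription factors, cAMP-CREB targets, regulatory and alternative macrophage markers, interferon genes, MAPK and JAK-STAT feedback inhibitors, prostanoid genes, Toll-like receptors, coagulation with matrix and growth factors, inflammasome and cell death, glycolysis, cholesterol, cell cycle and housekeeping. The other 8 held markers of macrophages, neutrophils, dendritic cells, B cells, T and NK cells, mast cells and basophils, erythroid cells, and fibroblasts and stroma. They held 392 genes, 9 of them in more than 1 list. Each list was tested against the other genes with camera (preset correlation 0.01), with camera using an estimated correlation, and with fry, which asks whether the genes of a list move one way without comparing them with other genes. Adjustment ran over the lists of a comparison. Members were also adjusted over the list alone. Listed genes that are not among the 18755 genes were not analysed here.

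Genes were named by a fixed rule: in each comparison the 8 largest rises and 8 largest falls among genes that passed and whose arrays did not overlap between the groups, leaving out unnamed predicted genes and small RNA genes; 18 genes given in every comparison; and the members of a list with the largest changes. Samples, comparisons, lists, this rule and most alternatives were chosen before the data were examined. Cyclic loess normalization, and the 2-fold threshold joined with each other alternative, were added after seeing the data.

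The alternatives were quantile normalization, equal array medians, a trended and robust variance, array weights, fits of the 2 groups alone, leaving out the dimmest genes by mean over all arrays (below the tertile boundary, or below the median), all probe sets, the mean of a gene's probe sets, a 2-fold threshold, replicate number as a block and each array left out in turn. Replicate numbers are not said to pair the arrays, so the comparisons were unpaired. The pipeline was tested on simulated data of 18755 genes with 200 changed. It recovered 70% to 78% of changes of 0.5 on the log2 scale, 98% to 100% of changes of 1 and 4% to 10% of changes of 0.25, with 5 to 8 false calls per comparison. The simulated noise was independent between genes and between arrays. It held no shift that follows the level of a gene and no likeness between arrays of the same replicate number. These rates therefore do not measure the false calls in the real arrays.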

Results

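Transcript levels were measured with whole-transcript arrays in macrophages grown from the bone marrow of C57Bl/6 mice. The cells were left untreated, stimulated for 1 hour with 100 ng/ml lipopolysaccharide (LPS, a bacterial cell wall component sensed through Toll-like receptors), or stimulated for 1 hour with the same dose of LPS together with 10 µM prostaglandin E (PGE, a lipid mediator, some of whose receptors raise cyclic AMP). The labels do not say which prostaglandin E was used. There were 4 untreated arrays, 3 LPS arrays and 4 LPS plus PGE arrays, and 18755 genes were tested. Values are on a log2 scale, so a difference of 1 is a 2-fold change. Arrays of 1 group correlated across genes at 0.996 to 0.998, and arrays of different groups at 0.980 to 0.993; genes are not independent replicates. The median SD of a gene was 0.107 in untreated, 0.121 in LPS and 0.102 in LPS plus PGE arrays. Each change below is a log2 fold change ± SE from the limma fit over all 11 arrays, with Benjamini-Hochberg adjusted p-values. The number of arrays limits the precision.

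The comparison of LPS with untreated cells asked which transcripts an hour of LPS alters in resting macrophages. Most of the listed inflammatory cytokines (13 of 20), chemokines (16 of 20) and MAPK and JAK-STAT feedback inhibitors (19 of 24) rose, and the largest falls were smaller than the largest rises. The largest rises were those of the cytokine Il1a (7.30 ± 0.21, or 158-fold), the neutrophil-attracting chemokine Cxcl2 (7.03 ± 0.12), the cytokine Il1b (6.87 ± 0.15) and the costimulatory ligand Tnfsf9 (6.83 ± 0.10). Cxcl1, another neutrophil attractant, rose by 6.32 ± 0.20, the prostaglandin-synthesising enzyme Ptgs2 by 5.99 ± 0.09, the cytokine signalling inhibitor Socs3 by 5.90 ± 0.12 and the chemokine Cxcl10 by 5.65 ± 0.15. Their limma adjusted p-values ran from 1.95e-12 to 3.34e-10. The steepest named falls were those of zinc finger genes, Zfp870 (-1.82 ± 0.16), Zfp39 (-1.80 ± 0.12), Zfp763 (-1.78 ± 0.13), Zfp273 (-1.72 ± 0.11) and Zfp128 (-1.72 ± 0.13). Dnajc28 (-1.73 ± 0.09), the glucocorticoid-induced gene Tsc22d3 (-1.68 ± 0.07) and the arrestin-related gene Arrdc3 (-1.63 ± 0.13) fell as well.

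In all, 2483 of 18755 genes (13.2%) passed the limma adjusted p of 0.05, of which 1229 rose and 1254 fell. Changes of at least 2-fold were found for 362 of them, 294 rises and 68 falls. Over all probe sets, with those lacking a gene name, the balance was the opposite (414 rises and 638 falls of at least 2-fold). Probe sets lacking a gene name gave 90 of these rises and 558 of these falls, so the opposite balance came from them. The median change of all genes was -0.015.

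Among genes chosen before the data were examined, the anti-inflammatory cytokine Il10 rose from 4.65 ± 0.28 (SD, n = 4) in untreated arrays to 10.00 in LPS arrays, a change of 5.36 ± 0.14. Tnf, an early inflammatory cytokine already at 8.55 in untreated cells, rose by 4.51 ± 0.07 to 13.07. The cytokine genes Il12b (5.25 ± 0.18), Il6 (3.66 ± 0.13) and Ifnb1 (3.59 ± 0.15) rose too. The untreated level of Il6 (3.57) lay below the lower quartile of those arrays (3.82 to 3.90), as did that of Lif (3.73), and that of Ifnb1 (3.83) lay within it. Background was not measured here and so low a level was not told from none, so the changes of these 3 genes against untreated are read as lower limits. Of the NR4A orphan nuclear receptors, Nr4a1 rose by 3.88 ± 0.10 and Nr4a3 by 2.63 ± 0.12, while Nr4a2 rose by only 0.46 ± 0.09. The phosphatase gene Dusp1 rose by 2.80 ± 0.06, the prostaglandin E receptor gene Ptger4 by 1.93 ± 0.09 and the ligand gene Tnfsf14 by 1.30 ± 0.18. The kinase gene Sik1 fell (-0.64 ± 0.09). The receptor gene Ptger2 also passed the test with a lower level (-0.34 ± 0.08, limma adjusted p = 0.0131), but without LPS replicate 2 its adjusted p was 0.0563. Crem (0.00 ± 0.09, limma adjusted p = 0.987), Arg1 (0.00 ± 0.13, limma adjusted p = 0.999) and Sphk1 (0.37 ± 0.12, limma adjusted p = 0.075) did not pass.

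Grouped by the lists fixed beforehand, all 17 measured genes of NF-kB feedback and signalling rose, 17 also when adjusted over the list alone. They were led by Nfkbiz (5.57 ± 0.12) and the inhibitors Tnfaip3 (4.30 ± 0.08) and Nfkbia (3.13 ± 0.06). Of 20 inflammatory cytokines 13 rose (14 adjusted over the list alone), of 20 chemokines 16 rose (16 adjusted over the list alone, with Ccl2 at 5.62 ± 0.13), and none of either list fell. Among 22 immediate-early transcription factors 19 rose (22 adjusted over the list alone), with Egr1 at 4.89 ± 0.11, Csrnp1 at 4.27 ± 0.08 and Maff at 3.82 ± 0.13. Among 24 MAPK and JAK-STAT feedback inhibitors 19 rose (21 rose and 1 fell adjusted over the list alone), including the phosphatases Dusp5 (4.40 ± 0.07) and Dusp2 (3.81 ± 0.10). The camera adjusted p-values of these lists lay between 1.51e-40 and 9.92e-23, and all 5 passed with an estimated correlation (adjusted p from 3.13e-05 to 0.00283).

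Of 23 cAMP-CREB targets, 11 rose and 2 fell (12 and 2 adjusted over the list alone), with the small GTPase Gem at 5.16 ± 0.09, Fosb at 3.27 ± 0.12 and the phosphodiesterase Pde4b at 2.93 ± 0.09 (camera adjusted p = 7.42e-11). Of 20 regulatory and alternative macrophage markers, 7 rose and 1 fell (8 and 1 adjusted over the list alone), among them Il1rn, the receptor antagonist of interleukin signalling (2.12 ± 0.12, list camera adjusted p = 3.04e-05). Of 21 genes for coagulation, matrix and growth factors, 13 rose (14 adjusted over the list alone), with tissue factor F3 at 3.49 ± 0.15 and the collagenase Mmp13 at 2.77 ± 0.15 (camera adjusted p = 1.35e-13). Of 16 inflammasome and cell death genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone), with Phlda1 at 4.04 ± 0.12 and the inflammasome sensor Nlrp3 at 3.02 ± 0.09 (camera adjusted p = 2.26e-10). Of 21 Toll-like receptors and adaptors, 10 rose and 3 fell (11 and 6 adjusted over the list alone; 5 falls after quantile normalization), with Tlr2 at 2.07 ± 0.13 and Nod2 at 1.77 ± 0.09 (camera adjusted p = 0.00677). With an estimated correlation the adjusted p-values of these 5 lists ran from 0.00102 to 0.0298.

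Interferon-beta and interferon-stimulated genes had 11 rises and 2 falls among 25 (12 and 2 adjusted over the list alone), with the GTPase gene Gbp5 at 4.04 ± 0.14 and the transcription factor Irf1 at 2.58 ± 0.09. Their camera adjusted p was 1.47e-07, and the adjusted p was 0.0925 with an estimated correlation. Of 17 cell cycle genes 3 rose (3 adjusted over the list alone), among them Mki67 (0.88 ± 0.10), a list with a camera adjusted p of 0.000778 and an adjusted p of 0.41 with an estimated correlation. Of 18 glycolysis and hypoxia genes 4 rose (4 adjusted over the list alone), with the itaconate-producing enzyme Acod1 at 5.32 ± 0.17 and the glucose transporter Slc2a1 at 0.70 ± 0.07. That list had a camera adjusted p of 0.0272, and an adjusted p of 0.221 with an estimated correlation. Of 18 prostanoid synthesis and receptor genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone), and beside Ptgs2 and Ptger4 the phospholipase Pla2g4a was higher (0.39 ± 0.08). Its camera adjusted p was 0.0421, with an adjusted p of 0.221 with an estimated correlation and of 0.142 without LPS replicate 1. The prostanoid call also ended without untreated replicate 1 (0.0737), untreated replicate 2 (0.07) or LPS plus PGE replicate 4 (0.0509). The glycolysis call ended without LPS replicate 1 (0.0579) or untreated replicate 3 (0.0505). Both calls also ended after quantile normalization (0.0517 for prostanoid, 0.0522 for glycolysis genes) and with the dimmest genes left out (0.0791 and 0.0595).

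Cholesterol synthesis and efflux genes did not pass as a list (camera adjusted p = 0.0985; 0.0438 without LPS replicate 1), with 4 rises and 1 fall among 15 (4 and 3 adjusted over the list alone), the largest that of the sterol sensor Insig1 (0.71 ± 0.06). No housekeeping gene of 14 passed, alone or over the list alone. Of the markers of other cells, those of dendritic cells had 2 rises among 14 (2 adjusted over the list alone), with H2-Eb1 at 0.39 ± 0.08 (camera adjusted p = 0.0421, but adjusted p = 0.0925 with an estimated correlation and 0.0793 without untreated replicate 1). That call also ended without untreated replicate 4 (0.0642), LPS replicate 2 (0.0502) or LPS replicate 3 (0.0656), and with the dimmest genes left out (0.0791). Among 13 macrophage markers, Cd14 (1.64 ± 0.06) and Msr1 (0.29 ± 0.07) rose (camera adjusted p = 0.67), although the median of that list was -0.05 and its mean 0.10. Neutrophil markers had 2 rises among 12, erythroid markers 1 fall among 8, stromal markers 1 rise and 1 fall among 12, and B cell, T and NK cell and mast cell markers none. The same counts were found adjusted over the list alone, and the camera adjusted p-values of these 6 lists ran from 0.166 to 0.58.

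**Figure D1:**
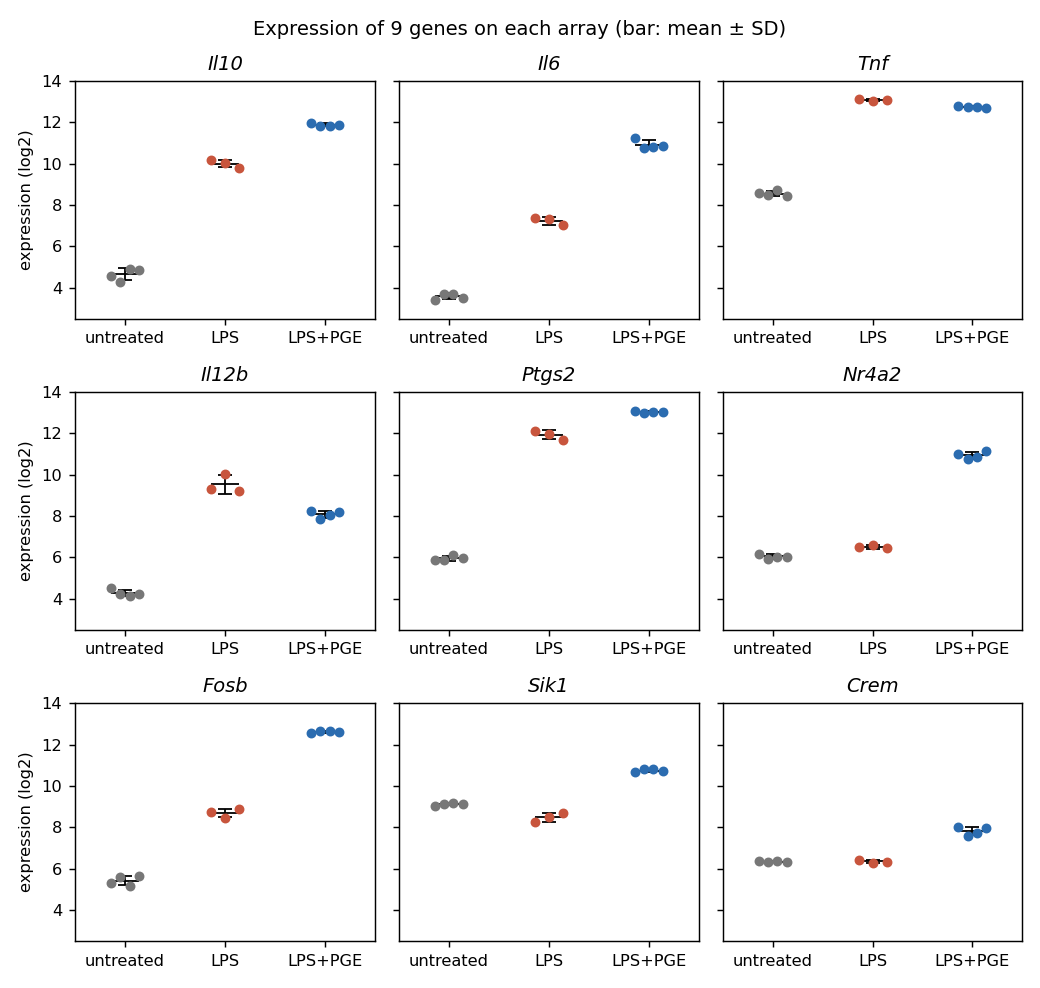
Expression (log2) of 9 genes on each array of the 3 groups; each point is an array, the black bar the mean and the whiskers the SD. Il10, Il6, Ptgs2, Nr4a2, Fosb, Sik1 and Crem were higher on every LPS plus PGE array than on any LPS array, and Tnf and Il12b were lower.

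The comparison of LPS plus PGE with untreated cells asked what the combined stimulus alters. The same cytokines led it, joined by genes that LPS alone had raised less. Il1a rose by 7.72 ± 0.20 (210-fold), Il6 by 7.33 ± 0.12, Il1b by 7.33 ± 0.14 and Il10 by 7.23 ± 0.13. The transcription factor gene Fosb rose by 7.21 ± 0.11, Cxcl2 by 7.16 ± 0.11, Ptgs2 by 7.09 ± 0.09 and Tnfsf9 by 6.84 ± 0.10, with limma adjusted p-values of at most 3.11e-11. The steepest named falls were those of Dnajc28 (-2.33 ± 0.09), Zfp72 (-2.27 ± 0.18), Zfp273 (-2.22 ± 0.10), Zfp455 (-2.19 ± 0.24), Zfp418 (-2.06 ± 0.15), Zfp329 (-2.05 ± 0.11), Zfp763 (-2.04 ± 0.12) and Zfp760 (-1.99 ± 0.12).

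Under the combined stimulus 5946 of 18755 genes (31.7%) passed, of which 2587 rose and 3359 fell, and 557 changed at least 2-fold (349 rises, 208 falls). Over all probe sets the balance was again the opposite, with 516 rises and 1026 falls of at least 2-fold. Probe sets lacking a gene name gave 126 of these rises and 775 of these falls, so they again made that balance. The rises and falls followed the level of the gene: the median change was 0.14 for genes with a mean below 5.92 and -0.11 for those above it. After cyclic loess normalization, chosen after seeing the data, 3897 genes passed. With all array medians made equal, the median of all genes moved to 0.143 and the calls split into 5747 rises and 1724 falls; with the dimmest genes left out they split into 1759 and 3743, and with a stricter filter at the median level into 998 and 3721.

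The genes chosen beforehand gave a rise of 6.60 ± 0.11 for Nr4a3, 5.96 ± 0.09 for Nr4a1 and 4.90 ± 0.09 for Nr4a2. Tnf rose by 4.18 ± 0.07, Il12b by 3.81 ± 0.16, Ifnb1 by 3.05 ± 0.14 and Dusp1 by 3.03 ± 0.06. Tnfsf14 rose by 2.07 ± 0.17, Sik1 by 1.62 ± 0.09, Crem by 1.48 ± 0.09, Ptger4 by 1.32 ± 0.08 and the sphingosine kinase gene Sphk1 by 1.11 ± 0.12. Ptger2 fell (-0.68 ± 0.07). Arg1, an arginine-degrading enzyme, did not pass (0.10 ± 0.12, limma adjusted p = 0.544).

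All 17 measured genes of NF-kB feedback and signalling rose again (17 adjusted over the list alone), among them Nfkbiz (5.55 ± 0.11), Tnfaip3 (4.33 ± 0.08) and the early response gene Ier3 (4.05 ± 0.11). Of the inflammatory cytokines 16 of 20 rose (17 adjusted over the list alone), and of the chemokines 16 of 20 (16 rose and 1 fell adjusted over the list alone), with Cxcl1 at 6.50 ± 0.18. Immediate-early transcription factors had 19 rises and 2 falls among 22 (20 and 2 adjusted over the list alone), with Egr1 at 5.02 ± 0.10. Of 24 MAPK and JAK-STAT feedback inhibitors, 19 rose and 1 fell (19 and 1 adjusted over the list alone), with the phosphatase gene Dusp14 at 5.78 ± 0.19. Of 23 cAMP-CREB targets 16 rose (16 adjusted over the list alone), with Gem at 5.80 ± 0.08. Regulatory and alternative markers had 10 rises and 2 falls among 20 (10 and 2 adjusted over the list alone), with the transcription factor Nfil3 at 4.20 ± 0.09 and Il1rn at 3.69 ± 0.11. Of 21 coagulation, matrix and growth factor genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with Serpinb2, an inhibitor of plasminogen activators, at 4.09 ± 0.13. The camera adjusted p-values of these 8 lists ran from 1.68e-26 to 2.48e-06, and with an estimated correlation from 0.000181 to 0.00825.

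Interferon genes had 13 rises and 3 falls among 25 (13 and 4 adjusted over the list alone; Isg15 at 2.76 ± 0.15), with a camera adjusted p of 0.000268 and an adjusted p of 0.261 with an estimated correlation. Inflammasome genes had 7 rises and 2 falls among 16 (8 and 4 adjusted over the list alone; Phlda1 at 5.27 ± 0.11), with a camera adjusted p of 0.00721 and an adjusted p of 0.132 with an estimated correlation. Glycolysis genes had 5 rises among 18 (5 adjusted over the list alone; Acod1 at 4.94 ± 0.16, Slc2a1 at 1.46 ± 0.07, the lactate transporter Slc16a3 at 1.27 ± 0.09), with a camera adjusted p of 0.0263 and an adjusted p of 0.257 with an estimated correlation; without LPS plus PGE replicate 4 the camera adjusted p was 0.05 and no longer passed. Mast cell and basophil markers had 2 rises among 10 (2 adjusted over the list alone), the histamine-producing enzyme Hdc (1.73 ± 0.09) and the transcription factor Gata2 (1.34 ± 0.13). Their camera adjusted p was 0.0263, with an adjusted p of 0.172 with an estimated correlation, of 0.0514 with equal array medians and of 0.255 after cyclic loess normalization. The Toll-like receptor list did not pass (camera adjusted p = 0.635), with 5 rises and 8 falls among 21 (5 and 10 adjusted over the list alone), but 5 rises and 3 falls after cyclic loess normalization; Tlr2 rose by 2.52 ± 0.12, the LPS co-receptor Cd14 by 2.22 ± 0.06 and Nod2 by 1.94 ± 0.09, and the adaptor Tirap fell (-1.06 ± 0.08). Its median was -0.17 and its mean 0.17. The prostanoid list (4 rises and 2 falls among 18, 4 and 3 adjusted over the list alone, camera adjusted p = 0.536) and the cholesterol list (5 and 5 among 15, 5 and 6 adjusted over the list alone, camera adjusted p = 0.808; 6 and 3 after cyclic loess normalization) did not pass either. Cell cycle genes had 2 rises among 17 (2 adjusted over the list alone, camera adjusted p = 0.116), and that list passed without untreated replicate 1 (0.00234) or LPS plus PGE replicate 2 (0.0416). The cell cycle list also passed with replicate number as a block (0.0268), after quantile (0.00807) or cyclic loess normalization (0.00233, with 4 rises) and with the dimmest genes left out (0.0169). Of 14 housekeeping genes 1 fell (0 adjusted over the list alone, camera adjusted p = 0.293). Among the other marker lists, macrophage markers had 1 rise and 1 fall among 13, dendritic cell markers 4 rises and 1 fall among 14, T and NK cell markers 2 rises and 1 fall among 12, B cell markers 1 rise among 9 and stromal markers 1 rise among 12. No neutrophil or erythroid marker passed. Adjusted over the list alone the counts were the same, except that the macrophage fall and the B cell rise were lost. The camera adjusted p-values of these 7 lists ran from 0.285 to 0.913. In untreated arrays the median level of T and NK cell markers was 3.6 and that of mast cell markers 3.59. Both lay below the lower quartile of those arrays (3.82 to 3.90), where a low level was not told from none. The median and mean differed in sign for the prostanoid (-0.06 and 0.45), cholesterol (-0.06 and 0.01) and macrophage marker lists (-0.04 and 0.14).

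Both comparisons used the same untreated arrays. Of the 1229 genes that rose with LPS, 737 (60.0%) also rose with LPS plus PGE, against 169.5 for independent lists, and of the 1254 that fell, 976 (77.8%) also fell, against 224.6. Another 63 genes passed in both with opposite signs. With the 4 untreated arrays split, 2 for each comparison, the share was 55.2% to 67.0% for rises and 69.5% to 78.9% for falls over 6 splits.

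**Figure D2:**
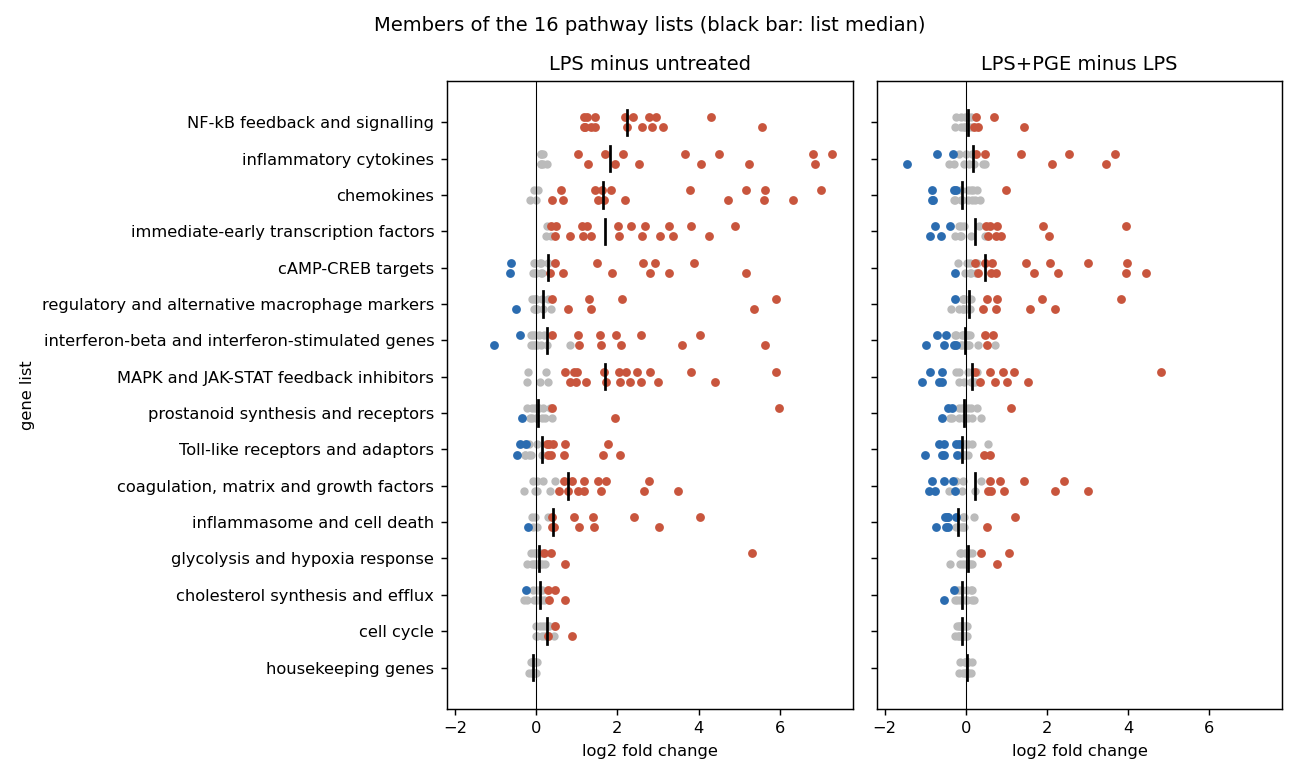
Log2 fold change of each measured member of the 16 pathway lists, for LPS minus untreated (left) and LPS plus PGE minus LPS (right); red and blue points passed the limma adjusted p of 0.05 with a rise or a fall, grey points did not, and black bars are list medians. The NF-kB list has a median of 2.23 on the left and 0.04 on the right, and the cAMP-CREB list 0.28 and 0.47.

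The comparison of LPS plus PGE with LPS alone asked what PGE changes in cells that also receive LPS; no group had PGE alone. The largest rises included members of the list of cAMP-CREB targets (Nr4a2, Nr4a3 and Fosb) and the cytokine genes Il6 and Lif. The phosphatase gene Dusp14 rose by 4.80 ± 0.20 (27.8-fold), Nr4a2 by 4.44 ± 0.09, Nr4a3 by 3.97 ± 0.12, Fosb by 3.94 ± 0.12 and Nfil3 by 3.81 ± 0.09. Il6 rose by 3.68 ± 0.13 (12.8-fold), the decoy receptor gene Il1r2 by 3.53 ± 0.15 and the cytokine gene Lif by 3.45 ± 0.22. The falls were smaller, the largest that of Mir146 (-2.17 ± 0.09), a small RNA gene that the naming rule left out. The named falls were led by the stress-responsive gene Nupr1 (-1.50 ± 0.15), Il12b (-1.44 ± 0.18) and the oxysterol-producing enzyme Ch25h (-1.42 ± 0.13). The oxidase gene Nox1 (-1.41 ± 0.17), Exoc3l4 (-1.28 ± 0.16) and the MHC-related gene H2-M2 (-1.24 ± 0.13) were among them. The limma adjusted p-values of these 14 named genes, Mir146 not counted, ran from 1.86e-10 to 0.000343. The non-coding gene Dleu2 (-1.38 ± 0.38, limma adjusted p = 0.0234) and Zfp975 (-1.25 ± 0.30, limma adjusted p = 0.0127) fell as well; Dleu2 was at 3.26 on LPS plus PGE arrays, below their lower quartile (4.00 to 4.05), so the size of its fall is read as a lower limit. Without LPS replicate 1 the adjusted p of Dleu2 was 0.0771, without LPS plus PGE replicate 1 it was 0.0593, and without LPS replicate 3 that of Zfp975 was 0.0503.

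Il10 rose from 10.00 to 11.88 (1.88 ± 0.14, limma adjusted p = 4.15e-06). Ptgs2 rose by 1.11 ± 0.09, Sik1 by 2.26 ± 0.09, Nr4a1 by 2.07 ± 0.10, Crem by 1.48 ± 0.09 and Sphk1 by 0.75 ± 0.12. The receptor gene Ptger4 fell (-0.60 ± 0.09, limma adjusted p = 0.00116). Tnf fell slightly (-0.33 ± 0.07, limma adjusted p = 0.00924). That call stayed after quantile (-0.37, adjusted p = 0.00996) and cyclic loess normalization (-0.32, adjusted p = 0.0164). It ended with equal array medians (-0.17, adjusted p = 0.114), a setting that moved the median of all genes up as well. Tnfsf14 (0.77 ± 0.18, limma adjusted p = 0.0114) and Dusp1 (0.23 ± 0.06, limma adjusted p = 0.0195) passed with higher values, and without LPS replicate 3 their adjusted p-values were 0.0511 and 0.0579. Il1b differed by 0.46 ± 0.15 (limma adjusted p = 0.0414). Its adjusted p was 0.127 without LPS replicate 3, and over 0.05 without any other single array except untreated replicates 1, 2 and 3. For Ifnb1 the difference was -0.54 ± 0.15 (limma adjusted p = 0.022, but 0.146 after quantile and 0.0437 after cyclic loess normalization). Its adjusted p was 0.074 without LPS replicate 2, 0.0724 without LPS replicate 3 and 0.0505 without LPS plus PGE replicate 4. For Ptger2 it was -0.34 ± 0.08 (limma adjusted p = 0.0107, but 0.255 after quantile normalization). Arg1 did not pass (0.10 ± 0.13, limma adjusted p = 0.593).

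Over all genes, 4641 of 18755 (24.7%) passed, 2225 rises and 2416 falls, but 4507 of them changed under 2-fold. Most of these small changes followed the level of the gene: genes with a mean below 5.92 had a median change of 0.14, with 1824 rises and 259 falls, and genes above it a median of -0.11, with 401 rises and 2157 falls. LPS against untreated showed no such split (medians -0.01 and -0.02). Quantile normalization gave 1899 calls (932 rises, 967 falls), of which 1575 were among the 4641, and cyclic loess normalization, chosen after seeing the data, 2173 (1135 and 1038), of which 1795 were. Equal array medians moved the median of all genes to 0.154 and the split to 5850 rises and 718 falls; with the dimmest genes left out the split was 1260 and 2828, and with a stricter filter at the median level 503 and 2842. Without LPS replicate 3 the count was 2945. The 134 changes of at least 2-fold, 106 rises and 28 falls, lost fewer calls. After quantile normalization 132 still passed the adjusted p, and after cyclic loess normalization 133. After each of these, 122 of the 134 also stayed at least 2-fold. Over all probe sets there were 354 rises and 263 falls of at least 2-fold, and with equal array medians 157 and 17.

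**Figure D3:**
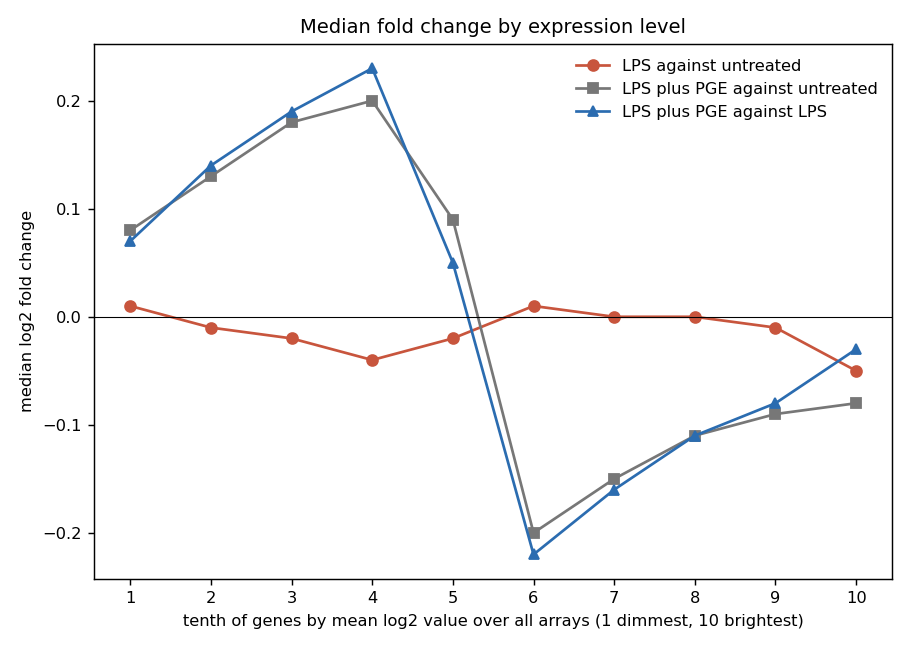
Median log2 fold change of the genes in each of 10 equal bins of the mean log2 value, for the 3 comparisons. In LPS plus PGE against LPS the median runs from 0.23 in bin 4 to -0.22 in bin 6, while in LPS against untreated every bin lies between -0.05 and 0.01.

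By list, 14 of 23 cAMP-CREB targets rose and 1 fell (15 and 1 adjusted over the list alone), among them Nr4a2, Nr4a3, Fosb and the matrix protein gene Thbs1 (3.01 ± 0.14). The list passed with a camera adjusted p of 1.22e-12, and with an adjusted p of 0.0028 with an estimated correlation. Of 20 regulatory and alternative macrophage markers, 8 rose and 1 fell (8 and 1 adjusted over the list alone), among them Nfil3, the growth factor Vegfa (2.20 ± 0.09) and Il1rn (1.57 ± 0.12). That list had a camera adjusted p of 0.00496, and an adjusted p of 0.106 with an estimated correlation. Vegfa also promotes vessel growth and Nfil3 is a broadly acting repressor, so the members that moved are not macrophage markers alone. No other list passed over all arrays. Leaving out arrays brought the number of lists past the threshold to 6 without LPS replicate 3, 4 without LPS replicate 1 or LPS plus PGE replicate 1, and 3 without LPS plus PGE replicate 2 or 3.

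Inflammatory cytokines went both ways, with 7 rises and 3 falls among 20 (7 and 3 adjusted over the list alone, camera adjusted p = 0.0634). Beside Il6 and Lif, the cytokine genes Osm (2.55 ± 0.10) and Il23a (2.12 ± 0.15) rose. Of 20 chemokines, Ccl17 rose (0.98 ± 0.13) and 5 fell (1 and 5 adjusted over the list alone), among them the T cell and monocyte attractants Ccl12 (-0.83 ± 0.18) and Ccl4 (-0.81 ± 0.10) (camera adjusted p = 0.305). Ccl22 passed as well (-0.84 ± 0.23, limma adjusted p = 0.0218), but its adjusted p was 0.102 after quantile and 0.0462 after cyclic loess normalization. It was 0.0602 without LPS replicate 1, 0.0669 without LPS replicate 2 and 0.0536 without LPS plus PGE replicate 3. Immediate-early transcription factors had 9 rises and 4 falls among 22 (11 and 4 adjusted over the list alone, camera adjusted p = 0.0683), with Fosl2 at 2.05 ± 0.07, Klf4 at 1.90 ± 0.12 and Atf3 lower (-0.88 ± 0.10). MAPK and JAK-STAT feedback inhibitors had 9 rises and 5 falls among 24 (12 and 6 adjusted over the list alone, camera adjusted p = 0.0788), with the cytokine signalling inhibitors Cish at 1.54 ± 0.13 and Socs1 at 1.19 ± 0.15, and the growth arrest gene Gadd45a lower (-1.07 ± 0.10). After quantile normalization the cytokine (0.00382), immediate-early (0.00282), MAPK (0.00382) and glycolysis (0.0372) lists passed by camera adjusted p. After cyclic loess normalization they passed as well (0.00588, 0.000913, 0.00414 and 0.024), and so they did with the dimmest genes left out (0.00158, 0.00158, 0.00245 and 0.033). With the dimmest genes left out the NF-kB (0.0146), coagulation (0.011) and mast cell lists (0.0073) passed too.

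NF-kB feedback genes had 5 rises among 17 (5 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.189), with Ier3 at 1.44 ± 0.12 and Nfkbie at 0.70 ± 0.08; after cyclic loess normalization the list passed (adjusted p = 0.00835). Coagulation, matrix and growth factor genes had 9 rises and 6 falls among 21 (10 and 6 adjusted over the list alone, camera adjusted p = 0.167), with the activin subunit gene Inhba at 2.41 ± 0.21 and Serpinb2 at 1.43 ± 0.14. Toll-like receptors and adaptors had 2 rises and 8 falls among 21 (3 and 9 adjusted over the list alone, camera adjusted p = 0.0683), but 2 and 5 after cyclic loess normalization, with the sensor Nod1 (-0.66 ± 0.09) and the adaptors Ticam1 (2-fold lower) and Tirap (-0.58 ± 0.08) lower and Cd14 higher (0.59 ± 0.06). Interferon genes had 3 rises and 6 falls among 25 (4 and 6 adjusted over the list alone, camera adjusted p = 0.433), but 2 and 2 after quantile and 3 and 3 after cyclic loess normalization, with Irf1 (-0.98 ± 0.09) and Gbp2 (-0.71 ± 0.12) lower; Rsad2 did not pass (0.72 ± 0.26, limma adjusted p = 0.0601). Inflammasome and cell death genes had 2 rises and 7 falls among 16 (2 and 7 adjusted over the list alone, camera adjusted p = 0.0683), but 2 and 4 after quantile or cyclic loess normalization, with Phlda1 higher (1.22 ± 0.12) and the death receptor gene Fas lower (-0.74 ± 0.10). Glycolysis genes had 3 rises among 18 (3 adjusted over the list alone, camera adjusted p = 0.3), among them Slc16a3 (1.05 ± 0.10) and Slc2a1 (0.76 ± 0.07). Prostanoid genes had 1 rise and 3 falls among 18 (1 and 3 adjusted over the list alone, camera adjusted p = 0.498), and cholesterol genes 2 falls among 15 (1 rise and 5 falls adjusted over the list alone, camera adjusted p = 0.261; 2 rises and 2 falls after cyclic loess normalization), led by Mylip (-0.55 ± 0.06). No cell cycle gene of 17 (camera adjusted p = 0.305) and no housekeeping gene of 14 (camera adjusted p = 0.761) passed. The medians of the interferon, T and NK cell and dendritic cell lists changed sign after quantile or cyclic loess normalization, and that of the prostanoid list after cyclic loess normalization.

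Of the markers of other cells, mast cell and basophil markers had 3 rises among 10 (3 adjusted over the list alone), with Hdc at 1.47 ± 0.10 and Gata2 at 1.23 ± 0.14 (camera adjusted p = 0.0683; 0.0373 without LPS replicate 3). Macrophage markers had 1 rise and 2 falls among 13, neutrophil markers 1 fall among 12 (the chemokine receptor Cxcr2, -0.45 ± 0.09), and dendritic cell markers 1 rise and 2 falls among 14, with the MHC regulator Ciita lower (-0.87 ± 0.10). Stromal markers had 2 rises and 1 fall among 12, the fall that of the collagen cross-linking enzyme Lox (-1.01 ± 0.09), which LPS had raised (0.96 ± 0.09). T and NK cell markers had 2 rises and 1 fall among 12, the fall that of Klrb1c (-0.98 ± 0.18), and B cell and erythroid markers 1 rise each. On LPS plus PGE arrays Cxcr2 (3.94) and Klrb1c (3.99) lay below the lower quartile (4.00 to 4.05), so the sizes of their falls are read as lower limits. Adjusted over the list alone the counts were the same, except that those of B cell and erythroid markers were 0. The median and mean differed in sign for the dendritic (0.05 and -0.03), T and NK cell (0.06 and -0.01) and stromal lists (0.11 and -0.03). The camera adjusted p-values of these 7 lists ran from 0.167 to 0.898. After quantile or cyclic loess normalization T and NK cell markers had 0 rises and 1 fall, dendritic cell and stromal markers 1 rise and 1 fall each, and B cell and erythroid markers none. In untreated arrays the median level was 3.6 for T and NK cell and 3.59 for mast cell markers, below the lower quartile (3.82 to 3.90). It was 4.14 for neutrophil, 4.31 for B cell and 4.47 for erythroid markers. At such levels most calls of this comparison were rises, so these counts do not tell a change of other cells.

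A further comparison asked whether genes that respond to treatment are raised or lowered by PGE. Genes chosen on LPS against untreated (at least 2-fold, limma adjusted p under 0.05) went both ways: of 294 raised genes PGE raised 92 further (31.3%) and lowered 76 (25.9%), with a median of 0.00, and of 68 lowered genes it lowered 26 further and raised 5, with a median of -0.23. In that choice the LPS arrays enter both differences. The choice fixed beforehand took genes at least 2-fold different between all 7 treated and the 4 untreated arrays. Of 307 raised genes in that set PGE raised 141 (45.9%), among them Nr4a3, Fosb and Il6, and lowered 54 (17.6%), among them Nupr1 and Il12b; 112 did not pass. Their median change with PGE was 0.24. Of 125 lowered genes, PGE lowered 77 (61.6%) and raised 3, with a median of -0.45. Of these 3, named after their values were seen, Tsc22d3 was raised the most (0.78). As 4 of the 7 treated arrays had PGE, an effect of PGE itself brings genes into this set: Thbs1 is in it, but LPS against untreated gave -0.08 ± 0.14 (limma adjusted p = 0.779). The larger share of rises in this set is therefore not a share of genes raised by LPS. With equal array medians 47 lowered genes were lowered further and 8 raised. Among all other genes 11.4% were raised and 12.5% lowered. These other genes were not matched on level. Over all genes there were 401 rises and 2157 falls above a mean of 5.92, and 1824 and 259 below it. Part of the excess of falls among the lowered genes may therefore go with the level, which was not tested against genes matched on level. Many of the 125 lowered genes have a symbol that is Zfp and a number. Of all 313 genes with such a symbol, 143 fell in LPS plus PGE against LPS (45.7%, against 12.3% of other genes). The excess of falls is therefore partly that of this gene family.

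**Figure D4:**
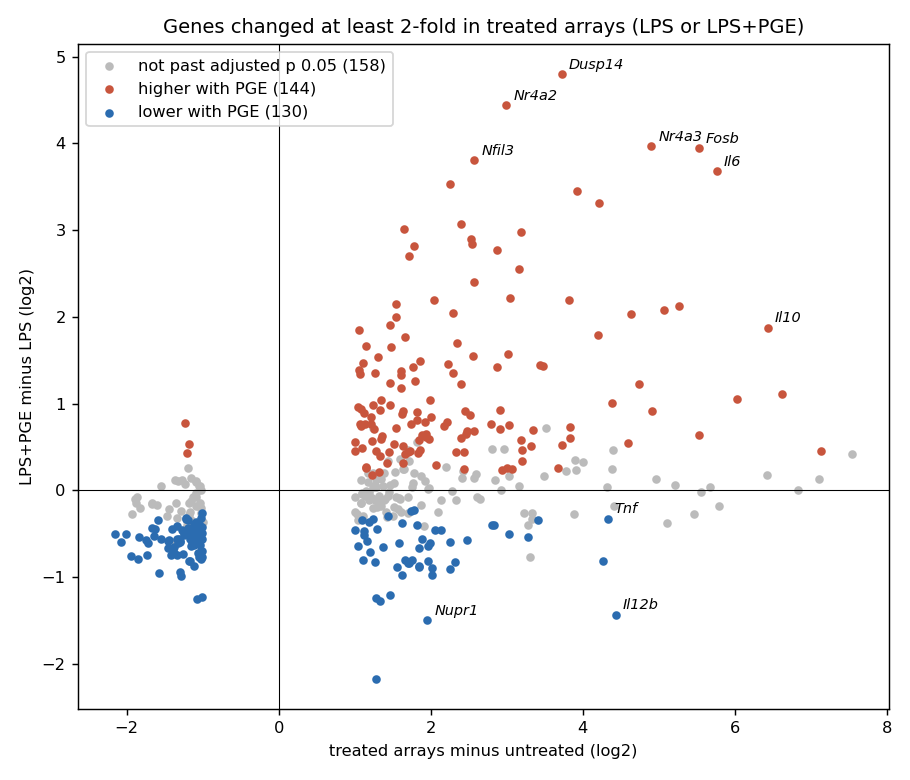
Change with PGE (LPS plus PGE minus LPS, log2) against the response to treatment (treated minus untreated, log2) for the responsive genes; red and blue points passed the limma adjusted p of 0.05 with higher or lower levels with PGE. Dusp14 (4.80), Nr4a2 (4.44) and Nr4a3 (3.97) lie highest, and Il12b (-1.44) and Nupr1 (-1.50) are among the raised genes that PGE lowered.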

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

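The tests of the level-dependent difference between arrays were chosen only after the result was seen; the counts over other splits of the arrays were chosen before. In 252 groups of 4 arrays (126 named genes in untreated and LPS plus PGE arrays), 10 held an array far from the others, where chance gives about 1 in 20, or 13. In untreated arrays, Atf3 was at 12.04 in replicate 1 (others 12.16 to 12.18), Dusp1 at 10.03 in replicate 1 (others 10.19 to 10.22), Ch25h at 4.05 in replicate 3 (others 4.51 to 4.58), Fas at 6.51 in replicate 3 (others 6.43 to 6.44) and Nfkbia at 9.44 in replicate 4 (others 9.57 to 9.59). In LPS plus PGE arrays, Il10 was at 11.98 in replicate 1 (others 11.84 to 11.86), Cxcr2 at 4.08 in replicate 2 (others 3.88 to 3.90), Nod2 at 7.29 in replicate 2 (others 7.56 to 7.58), Tnfaip3 at 12.18 in replicate 3 (others 12.12 to 12.13) and Ptger2 at 6.29 in replicate 4 (others 6.54 to 6.56).

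Signal also appeared in the 12296 probe sets without a gene name, which the comparisons did not use. At least 2-fold rises were found for 90 of them with LPS against untreated, 126 with LPS plus PGE against untreated and 234 with LPS plus PGE against LPS, beside 558, 775 and 225 falls.

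Most calls in LPS plus PGE against LPS were under 2-fold and followed the level of the gene. Of the 4507 such calls 68% were lost after quantile normalization, so a level-dependent difference between the arrays that the deposited normalization left in may account for much of them. A slight effect of PGE on many genes cannot be told apart from it, because the shift coincides with the group; 1662 of these calls stayed past the adjusted p after cyclic loess normalization. For calls of at least 2-fold that difference is argued against as the whole cause, since 122 of the 134 stayed at least 2-fold after quantile normalization. That 98.5% of them stayed past the adjusted p adds little. The median shift in bins of level lay between -0.22 and 0.23, too small to end most calls of that size.

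Each comparison was also fitted over the 35 splits of its arrays into groups of the same sizes. For the number of genes the real split of the 2 groups alone was the only 1 as large. It called 1884 genes in LPS against untreated, 6314 in LPS plus PGE against untreated and 3931 in LPS plus PGE against LPS. The highest other split called 0 in each. A chance split is argued against, but only as far as 1 in 35, the smallest share the splits allow. The same holds for changes of at least 2-fold (361, 557 and 135, against 0 in each) and for the treatment-responsive genes changed by PGE (275 against 0). The other splits mix the groups, so a real difference enters their spread and lowers their counts. The size of the gap to 0 is therefore not to be read as strength. The splits also exchange arrays across replicate numbers, which may mark a shared marrow. They say nothing of a cause other than chance. For the number of lists the splits say less, and they test no single list. In LPS against untreated the real split gave 15 and the highest other 14, too close to rest on. Chance cannot be excluded for the number of lists in LPS plus PGE against untreated, where 2 splits had as many (12, highest other 12), or in LPS plus PGE against LPS, where 17 splits did (2, highest other 8). In LPS plus PGE against LPS the highest other count, 8, was well above the real 2. A structure of the samples, a preset correlation that was too low or the mixing of the groups may give such a count. The cause was not tested.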

How the results depend on the processing

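Cyclic loess normalization and the 2-fold threshold joined with other alternatives were tests chosen only after the results were seen. Over all alternatives, 5979 values of named genes kept their direction and side of the threshold, 195 no longer passed, 130 newly passed, 23 moved and 0 reversed. For lists the numbers were 1177, 29, 55, 33 and 2. The 2 reversed list values were those of the Toll-like receptor list and the macrophage markers in LPS plus PGE against untreated. With fry both passed upward (adjusted p = 3.33e-05 and 0.000241), whereas camera pointed down without passing (adjusted p = 0.635 and 0.913). No list that had passed was therefore turned around. The number of genes past the adjusted p in LPS plus PGE against LPS was 1899 after quantile and 2173 after cyclic loess normalization, and that in LPS plus PGE against untreated was 3897 after cyclic loess normalization. Adding the 2-fold threshold left 362 genes in LPS against untreated, 557 in LPS plus PGE against untreated and 134 in LPS plus PGE against LPS, and with all probe sets these were 1052, 1542 and 617. More probe sets were tested there. Lists past the threshold in LPS plus PGE against LPS numbered 6 after quantile normalization, 7 after cyclic loess normalization, 9 without the dimmest genes, 1 with an estimated correlation and 13 with fry; with fry 20 passed in LPS plus PGE against untreated. Genes lowered by treatment and lowered further by PGE numbered 47 with equal array medians, 176 with all probe sets, 2 at 2-fold and 26 when chosen on LPS against untreated. Those lowered by treatment and raised by PGE numbered 8, 21, 0 and 5 in the same order, and 1 without genes below the median level. Genes raised by treatment and raised by PGE numbered 62 at 2-fold and 92 when chosen on LPS against untreated, and those lowered by PGE 6 at 2-fold. Except where a threshold or the number of genes tested differs by construction, the cause was not tested.

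With each array left out in turn, genes that passed ranged from 1925 to 2364 in LPS against untreated, from 4701 to 6143 in LPS plus PGE against untreated and from 2945 (without LPS replicate 3) to 4455 in LPS plus PGE against LPS. Changes of at least 2-fold ranged from 339 to 385, 549 to 585 and 125 to 146, and lists from 13 to 15, 11 to 13 and 2 to 6. Genes raised by treatment and raised by PGE ranged from 119 to 144, and those lowered by PGE from 41 to 55. Genes lowered by treatment and lowered further ranged from 57 to 90, and those raised by PGE from 1 (without LPS plus PGE replicate 1) to 3. With replicate number as a block 2454, 6124 and 4698 genes passed. The treated arrays include those with PGE. Background was not measured here, so what low signal limits was not tested.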

Other observations

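The tests on replicate numbers and on zinc finger genes were chosen only after the results were seen, and so were the microRNA genes named here. Of 295 probe sets annotated to microRNA genes, 7 rose and 4 fell at least 2-fold with LPS. Mir155 rose by 4.52 ± 0.25, Mir221 by 3.60 ± 0.10, Mir222 by 3.48 ± 0.16 and Mir146 by 2.52 ± 0.09 (limma adjusted p from 1.42e-10 to 1.03e-07), while Mir340 (-1.83 ± 0.17) and Mir181b-1 (-1.59 ± 0.16) fell. With LPS plus PGE against LPS, 3 rose and 5 fell at least 2-fold. Mir146 fell (-2.17 ± 0.09, limma adjusted p = 1.84e-08), as did Mir27b (-1.36 ± 0.10), Mir24-1 (-1.33 ± 0.13) and Mir23b (-1.29 ± 0.15), which lie in 1 cluster, and Mir15a (-1.21 ± 0.17). Mir212 (1.17 ± 0.09) and Mir132 (1.16 ± 0.16), neighbours in the genome, rose. Levels of Mir146 on untreated (2.80) and LPS plus PGE arrays (3.15), of Mir132 on LPS arrays (3.57) and of Mir340 on LPS arrays (2.33) lay below the lower quartiles of those arrays, so the sizes of these changes are read as lower limits. The probe sets do not separate host transcript from mature arm.

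Of 313 genes whose symbol is Zfp and a number, 144 fell after LPS (46.0%, against 6.0% of other genes) and 14 rose, with a median of -0.31. For LPS against untreated a level-dependent difference between arrays is argued against, since 0 of 10000 random lists matched on mean level had a median as low (lowest -0.05), and the median was -0.33 after quantile normalization, -0.29 after cyclic loess normalization and -0.34 with equal array medians. With LPS plus PGE against untreated 217 fell and the median was -0.55. With LPS plus PGE against LPS the median was -0.27, where matched lists had a median of -0.10 (lowest -0.15). After quantile or cyclic loess normalization it was -0.18, and the 143 falls became 80 after cyclic loess normalization, so part of that difference goes with the level shift. With equal array medians it was -0.11, but that setting moved the median of all genes up as well and says nothing of the level. A fast loss of short-lived transcripts may be a biological explanation, but no transcript stability was measured here, so it was not tested.

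The mean level of the Y-linked genes Eif2s3y, Kdm5d and Uty followed the replicate numbers of the labels: 3.71 for number 4, 6.75 for number 1, 7.40 for number 3 and 8.17 for number 2, and Xist ran the other way (11.70, 11.52, 11.39 and 10.74). Noise between arrays is argued against, since the largest range within a number was 0.37 and the smallest gap between numbers 0.65. Arrays with the same number may come from the same marrow, with that of numbers 1 to 3 mixed from both sexes: of all assignments of numbers to the LPS and LPS plus PGE arrays only 1, the real one, gave so small a spread (exact permutation p = 0.0017, one-sided, the smallest possible). The LPS group has no number 4, the number with the lowest Y-linked level, so both comparisons with that group are unbalanced in number. In LPS plus PGE against LPS the Y-linked genes were lower without passing. The differences were -1.24 for Eif2s3y, -1.14 for Kdm5d and -1.2 for Uty (limma adjusted p from 0.33 to 0.488). Over all genes, each of the 11 arrays correlated best, after group means were removed, with an array of its own number. The 10 same-number pairs had a median r of 0.13 (-0.02 to 0.21, across genes, which are not independent replicates), and 6 exceeded 0.1. The 30 other pairs had a median of -0.04 and reached at most 0.09. The fits were left unpaired because the labels do not say that numbers pair the arrays. They therefore leave out a pairing that these values point to. The counts with number as a block are given with the other alternatives.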
